A study of Mus musculus with 7 samples.

How the data were processed

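Gene expression was measured in brain tissue of C57BL/6 female mice on 7 Illumina bead arrays, on which short probes carried on beads capture biotin-labelled cRNA. Per the labels, 1 array held untreated control mice and 6 arrays held mice given an aqueous extract of Ephedra herba (the dried stems of Ephedra, which contain sympathomimetic alkaloids) by mouth once a day, at 50 or 1250 mg/kg, for 1, 3 or 10 days. Each combination of dose and day has 1 array and there are no replicates of a condition. The labels do not say how many mice each RNA sample came from, so the p-values below speak of these arrays and not of animals.

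The deposited values are log2 intensities from which the authors subtracted a constant for each array. No label gives the log base. It was read by hand: averaged over all arrays, the deposited value of a probe rises by 1 unit for each doubling of its mean intensity in a deposited table of linear intensities. The 7 columns of that table carry names that match no sample label and were to be left out of every step, so the base rests on a source that should not have been used. No comparison used them, but the size of each fold depends on the base. The background step, the scanner software and the rule by which the authors left probes blank are not given in the sources used here. Of 25697 probes, 13304 (51.8%) had a value on all 7 arrays and 12393 had none on any. The medians of the deposited values were 1.93 for the control, 1.92 and 1.92 for day 1 at 50 and 1250 mg/kg, 1.87 and 1.89 for day 3, and 1.90 and 1.87 for day 10. No detection p-value was used here. The change of a gene that is near the floor on one side may be understated or overstated, since the background step is not known.

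From these values the arrays were put on a common distribution by quantile normalization (limma 3.58.1 in R 4.3.3). The plan fixed before the data were examined had named normexp background correction of scanner intensities as the first step. It was not run because those intensities could not be tied to samples, and the deposited log2 values took their place. The filter was that of the authors. Probe names came from the annotation of the array platform, with symbols updated by Entrez number through an NCBI table for assembly GRCm38.p6, where all 12150 named probes matched. Of the 13304 probes, 12150 had 1 gene symbol, 0 had several and 1154 are unnamed here. Each of the 9009 genes was represented by its probe with the highest mean over all arrays, and 2273 genes had more than 1 probe. No genome coordinates are given because the build of the array annotation is not given in the sources used here.

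Changes of each treated array against the control are differences of normalized log2 intensity, with no test, because each side has 1 array. The 3 linear models were fitted with limma (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05). The dose model compared 3 arrays at 1250 with 3 at 50 mg/kg and held the day as a block. The day model compared 2 arrays of day 10 with 2 of day 1, held the dose as a block and let day 3 share the estimate of the spread. The model of treatment compared the 6 treated arrays with the 1 control, which was assumed to vary like the treated arrays. In the first 2 models the residual, with 2 degrees of freedom, also holds any difference of the dose effect between days. The eBayes step draws each gene's variance toward a trend shared by all genes, weighted there as 14.1 prior degrees of freedom. Standard errors and p-values for dose and day therefore rest mostly on that shared variance, most of all where a day is left out. Serpina1b had dose differences of 4.04, 1.32 and 1.47 on days 1, 3 and 10, beside a standard error of 0.33. The treatment model had a residual of 5 and a prior of 5.74 degrees of freedom. The block follows the day given by the labels. Deviations from the dose means of the arrays of a shared day correlated across genes at 0.58 on day 1, 0.70 on day 3 and 0.44 on day 10.

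For the 2 doses on each day, genes changed at least 1.5-fold in opposite directions were counted, and the correlation and covariance of the changes across genes were set beside 100 simulations of unchanged arrays that share a control. Before the data were examined, 36 gene lists were fixed, for responses to the extract and for markers of brain cell types, brain regions and neighbouring tissues. The 34 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of each model, and again with an estimated correlation. On single arrays a list's median was placed among those of 10000 random lists matched on mean expression. Liver, and heart and skeletal muscle, were added as lists after the results had been seen, so their values are no independent evidence.

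Named genes followed a rule fixed before the data were examined. They are the 10 highest and 10 lowest genes changed at least 1.5-fold one way in all 6 treated arrays, those changed at least 1.25-fold one way by dose on all 3 days, the 3 highest and 3 lowest of each array, the 5 highest and 5 lowest for day 10 against day 1 among genes changed at least 1.25-fold one way at both doses, the 4 with the largest opposite changes in each direction and on each day, and up to 4 members of a list. All 13 genes called for dose are named, and 4 of them (Fgg, Cyp2a5, Vapa and Ddit4) were chosen for that comparison after their values were seen. On simulated data with 200 of 9009 genes changed by 1 on the log2 scale, each of the 3 models recovered 100% of the changed genes. At a change of 0.5 the recovered share was 97.5% for dose, 79.5% for day and 63% for treatment. Between 11 and 14 unchanged genes were called in each simulation. The simulated noise was independent between arrays, with the variance of the dose model (median standard deviation 0.12) and no other effect of day or dose. The real treatment model had a median of 0.16 and held such effects, so these shares overstate its recovery. Myl2, at -2.12 ± 0.75, was not called there. The real dose and day models hold differences of the dose effect between days, which the simulations lack. The shares therefore overstate their recovery too, for genes with such differences. Apoa2, at 2.19 ± 0.43 for dose (adjusted p = 0.0634), and Myl2, at 1.27 ± 0.35 for day (adjusted p = 0.0685), were not called. Alternatives were the deposited values without quantile normalization, median scaling, a filter to the brightest 6424 of all probes, other fold thresholds, models without the block or the intensity trend, and models without arrays left out in turn. Models without the day 3 arrays or with the liver list as a covariate were added after the data were seen.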

Results

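The series asked how an oral extract of Ephedra herba changes gene expression in the mouse brain over days of dosing, and its title speaks of reciprocal regulation of genes. Intensities of 9009 named genes were compared on 7 arrays, which were 1 untreated control and 1 array for each of 2 doses (50 and 1250 mg/kg) on each of 3 days (1, 3 and 10). No condition was replicated, so differences between single arrays have no replicate check, and the number of arrays limits the precision throughout. Values are on the log2 scale, where a change of 1 is a doubling of intensity. All arrays correlated closely with the control across genes, from 0.982 for day 3 at 1250 mg/kg to 0.996 for day 1 at 50 mg/kg.

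Against the control, many of the largest changes on single arrays belonged to transcripts of other tissues or of single brain regions. Growth hormone (Gh) and prolactin (Prl), hormones of the anterior pituitary, were higher than in the control on day 1 at 50 mg/kg (by 2.54 and 2.72), on day 1 at 1250 mg/kg (3.30 and 3.21) and on day 3 at 50 mg/kg (2.24 and 2.51). They were lower on the other 3 treated arrays, where Gh differed by -0.76 to -0.88 and Prl by -1.39 to -1.72 and both lay near the floor of the values. Pcp2, a transcript of cerebellar Purkinje cells, was higher by 2.99 and 1.89 on day 3 and by 2.96 and 5.03 on day 10 at 50 and 1250 mg/kg, beside -0.66 and 0.36 on day 1. Apoa2 and Serpina1b, which encode plasma proteins made mainly in the liver, were higher by 4.35 and 3.96 on day 1 at 1250 mg/kg, by 3.18 and 3.78 on day 10 at 1250 mg/kg, and by 1.99 and 2.31 on day 10 at 50 mg/kg. Myl2 and Nppa, a myosin light chain and a natriuretic peptide of heart muscle, were lower on 5 of the 6 treated arrays, at -2.36 to -2.65 and -1.33 to -2.17. On day 10 at 50 mg/kg they differed by -0.076 and -0.44.

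**Figure D1:**
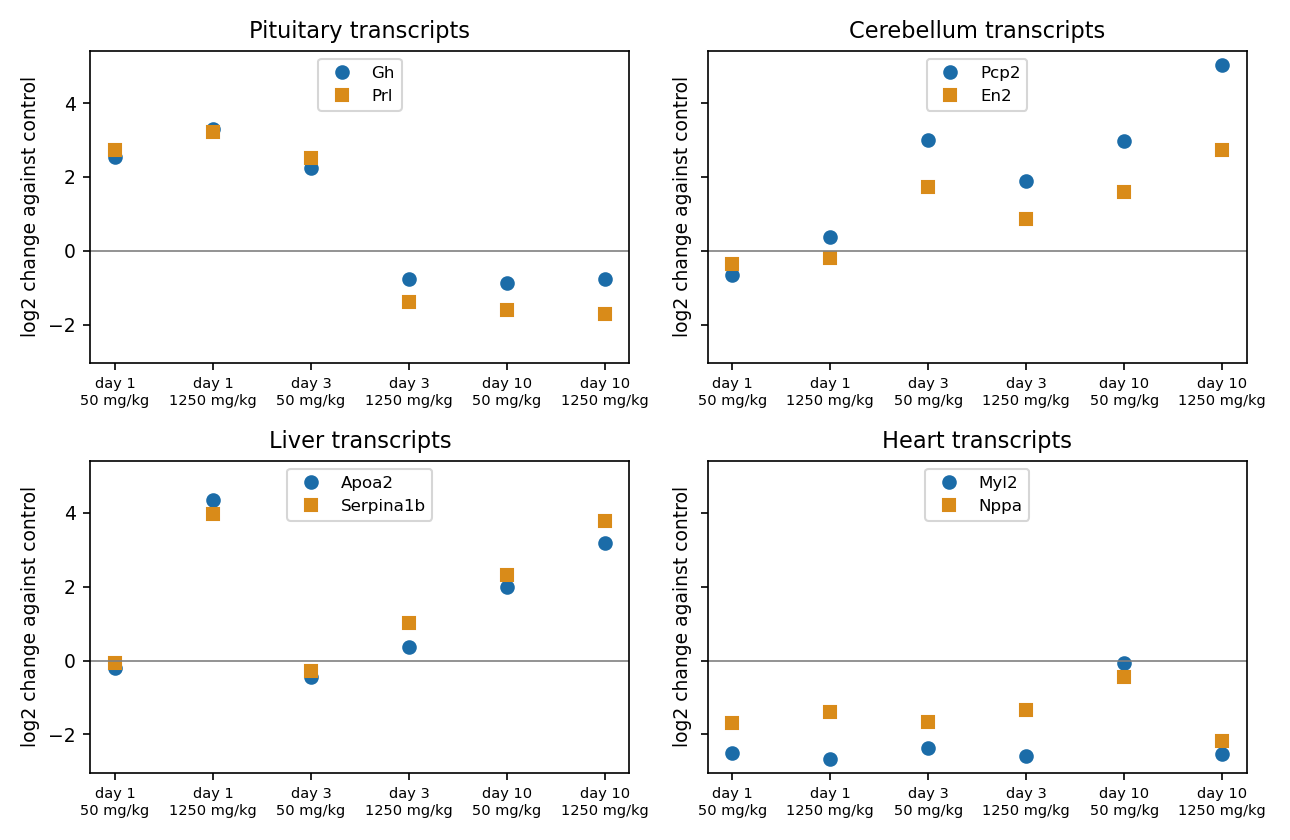
Log2 change against the control on each treated array, with 1 point per gene and array, for 2 transcripts each of pituitary, cerebellum, liver and heart. Gh and Prl lie above 0 on 3 arrays and below 0 on 3, Pcp2 reaches 5.03 on day 10 at 1250 mg/kg, Apoa2 reaches 4.35 on day 1 at 1250 mg/kg, and Myl2 lies near 0 only on day 10 at 50 mg/kg.

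The number of genes at least 2-fold higher or lower than in the control differed by day and by dose. On day 1, 3 genes were higher and 3 lower at 50 mg/kg, and 19 were higher and 5 lower at 1250 mg/kg. The other genes at the ends of the day 1 arrays were Xlr4a, 1.20 higher at 50 mg/kg, Ucn, a neuropeptide of the urocortin family, at -1.13 at 50 mg/kg, and the interferon-induced Ifit3 at -1.38 at 1250 mg/kg. Day 3 had the most, with 105 higher and 8 lower at 50 mg/kg and 139 higher and 8 lower at 1250 mg/kg. Highest there at 1250 mg/kg were Atp5a1, a subunit of mitochondrial ATP synthase, and Vapa, a protein of the endoplasmic reticulum membrane, both 2.02 above the control, and lowest at 50 mg/kg after Myl2 and Nppa was Myl4 at -1.26. On day 10, 8 genes were higher and 4 lower at 50 mg/kg, and 40 were higher and 8 lower at 1250 mg/kg. Among the lowest at 50 mg/kg were Arc, an immediate early gene of neuronal activity, at -1.35 and Avp, the precursor of vasopressin, at -1.19. In the deposited values the median change of all genes was -0.13 and -0.097 on the day 3 arrays. After quantile normalization it was -0.028 and -0.033, and changes are reported on that scale.

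For dose, 13 genes were higher at 1250 than at 50 mg/kg and 0 were lower. Of the 13, 9 encode proteins made mainly in the liver: Serpina1b, Kng1, Apoa1, Apoc1, Apoc3, Mat1a, Mup2, Fgg and Cyp2a5. Serpina1b, a protease inhibitor of plasma, differed by 2.28 ± 0.33 (standard error of the model, 3 arrays per dose, adjusted p = 0.00753), and Apoc1, an apolipoprotein, by 1.32 ± 0.17 (adjusted p = 0.00235). The other 4 were Sgk1 (0.68 ± 0.12, adjusted p = 0.0207) and Ddit4 (0.61 ± 0.10, adjusted p = 0.0173), both induced by glucocorticoids, the neutrophil transcript S100a8 (0.90 ± 0.13, adjusted p = 0.00753) and Vapa (0.65 ± 0.11, adjusted p = 0.0207). Each of the 13 was higher at 1250 mg/kg on 3 of 3 days. At 50 mg/kg on days 1 and 3, Serpina1b (-0.59 and -0.81), Kng1 (-0.69 and -0.63) and Mup2 (-0.81 and -0.55) lay near the floor of the values. Apoa2 was also higher on all 3 days (2.19 ± 0.43) but missed the threshold (adjusted p = 0.0634). It passed in the deposited values, after median scaling and without the arrays of any 1 day, and missed it with no intensity trend and with no day block. Cav1, the main protein of caveolae, was the only gene that met the fold rule for lower values on every day, at -0.40 ± 0.10 (adjusted p = 0.319).

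**Figure D2:**
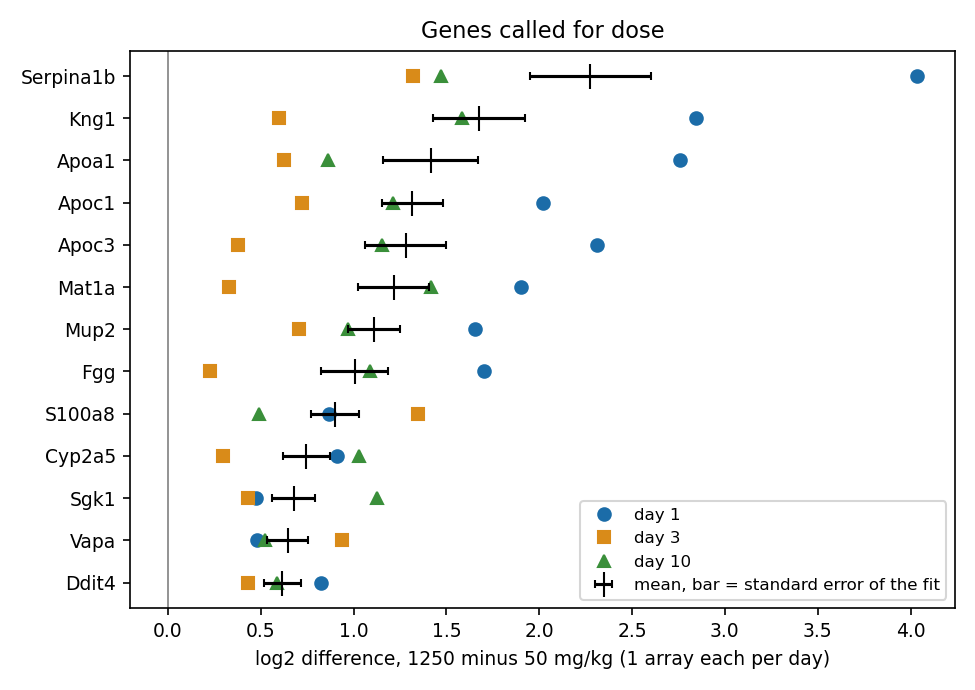
Log2 difference between 1250 and 50 mg/kg on each day for the 13 genes called for dose, with 1 array per dose and day. Points are days, and the black mark with its bar is the mean with the standard error of the model. That error rests mostly on a variance shared by all genes, so the bars can be narrower than the spread of the points. The day 1 difference of Serpina1b is 4.04 and that of Sgk1 is 0.48.

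The liver transcripts followed single arrays as well as the dose. The median change of the 24 measured genes of the liver list, which was written after the results had been seen, was 0.92 on day 1 and 0.87 on day 10 at 1250 mg/kg, 0.30 on day 10 at 50 mg/kg and 0.039 on day 3 at 1250 mg/kg. At 50 mg/kg it was -0.050 on day 1 and -0.16 on day 3, so it was higher at 1250 mg/kg on each day. In the dose model 24 of the 24 genes were higher at 1250 mg/kg. Mup2, Serpina1b and the Apoc genes belong to families of similar sequence, so a probe may also read a relative. The erythrocyte transcripts Hba-a1 and Alas2 were higher than in the control on the arrays with most liver signal, by 0.86 and 1.02 on day 1 and by 0.93 and 1.75 on day 10 at 1250 mg/kg. The dose count rested on a residual of 2 degrees of freedom and became 0 without the day block, 2 (Sgk1 and Ddit4) among the brightest 6424 probes, and 7, 45 and 31 without the arrays of day 1, day 3 and day 10, with 6, 12 and 12 of the 13 among them. Genes lower at 1250 mg/kg were called there too, 6 without day 3, led by Myl2 at -1.30, and 5 without day 10, led by Prl at -1.71 and Gh at -1.12. Those 3 led through 1 day each. Prl and Gh were higher at 1250 mg/kg on day 1 (0.48 and 0.77) and lower on day 3 (-3.90 and -3.00). Myl2 differed by -0.15 on day 1 and -2.46 on day 10. Such calls rest mostly on the variance shared by all genes and do not require the days to be alike. The sizes rested in part on day 1: without it, those that fell by over 1.5 times were 1.40 for Serpina1b, 1.09 for Kng1, 0.74 for Apoa1, 1.00 for Apoa2, 0.77 for Apoc3 and 0.66 for Fgg, the last 2 no longer called.

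Among the lists fixed in advance, the glucocorticoid-responsive genes were higher at the higher dose as a group. Of 17 measured, 16 were higher at 1250 mg/kg, with a median of 0.15. After Sgk1 and Ddit4 the largest values were those of Nfkbia, the inhibitor of NF-kappa-B (0.51 ± 0.10), and Angptl4 (0.40 ± 0.13). In the test over all genes 2 were called, Sgk1 and Ddit4, and 6 adjusted over the list alone. Sgk1 was no longer called without day 10, nor Ddit4 without day 1. Camera gave this list an adjusted p of 2.54e-09, and an adjusted p = 0.67 with an estimated correlation. On single arrays its median against the control was 0.19 and 0.26 on day 1, 0.15 and 0.39 on day 3 and -0.017 and 0.14 on day 10, at 50 and 1250 mg/kg. Sgk1 and Ddit4 were both 1.02 above the control on the array of day 1 at 1250 mg/kg, which also had high liver transcripts, and Sgk1 was 1.21 above it on day 3 at 1250 mg/kg, where the liver list lay near the control.

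Camera called 7 other lists, all higher at 1250 mg/kg, with small medians, and 0 of them with an estimated correlation. Olfactory bulb markers (15 measured, 13 higher, median 0.14, adjusted p = 0.00111, and 0.72 with an estimated correlation) were led by Doc2g at 0.64 ± 0.19 and Cdhr1 at 0.41 ± 0.16. Both were lower at 1250 mg/kg on day 10 (-0.13 and -0.33), and without day 10 their differences were 1.03 and 0.78. Cerebellar markers (12 measured, 9 higher, median 0.16, adjusted p = 0.00867, and 0.72 with an estimated correlation) were led by Pcp2 at 0.66 ± 0.34 and Zic1 at 0.46 ± 0.12, with a difference of -1.10 for Pcp2 on day 3. Without day 10 the differences turned to -0.037 for Pcp2 and -0.11 for Cbln1, and without day 3 that of Pcp2 was 1.54. Oxidative phosphorylation genes (49 measured, 36 higher, median 0.070, adjusted p = 0.00874, and 0.70 with an estimated correlation) included Ndufb2 at 0.29 ± 0.12 and Uqcrb at 0.27 ± 0.12. Of 18 circadian clock genes 14 were higher (adjusted p = 0.0151, and 0.70 with an estimated correlation), with Ciart at 0.46 ± 0.17, Nr1d2 at 0.33 ± 0.11 and Per1 at 0.31 ± 0.12. GABA signalling genes (13 measured, 10 higher, adjusted p = 0.0151, and 0.70 with an estimated correlation) included Vip at 0.32 ± 0.11. The oxidative stress list (24 measured, 16 higher, adjusted p = 0.0225, and 0.70 with an estimated correlation) was led by Gsta3 at 0.84 ± 0.16, a glutathione transferase that was 1.33 and 1.34 above the control on the 2 arrays with most liver signal. All 6 hindbrain markers were higher (adjusted p = 0.0225, and 0.70 with an estimated correlation), led by Tph2, the brain enzyme of serotonin synthesis, at 0.26 ± 0.11. Among the brightest 6424 probes the adjusted p was 0.164 for the oxidative stress list, 0.0547 for the clock and 0.0818 for oxidative phosphorylation, and the hindbrain list had too few members for the test, so these 4 calls were lost. The genes named from these 7 lists did not pass the test for dose one by one. In alternatives, Gsta3 passed in the deposited values, after median scaling and without day 3 or day 10. Doc2g passed without day 3 or day 10, Cdhr1 without day 10, and Pcp2, Cbln1, Zic1 and Ciart without day 3. Passes with a day left out rest mostly on the variance shared by all genes and do not require the remaining days to be alike. Doc2g passed without day 3 although its differences were 1.46 on day 1 and -0.13 on day 10. Adrenergic signalling genes (11 measured, 6 higher, adjusted p = 0.93) and dopamine signalling and striatal genes (19 measured, 12 higher, adjusted p = 0.69) were not called.

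For all treated arrays against the control, limma called 0 genes (162 at an unadjusted p under 0.05), and 0 genes were at least 1.5-fold changed one way on all 6 arrays. Camera at the preset correlation called 7 lists, each set against 1 control array, and 0 with an estimated correlation. Of 17 interferon-stimulated genes 15 were lower than in the control, led by Usp18 (-0.74 ± 0.21) and Isg15 (-0.63 ± 0.20), which were lower on 6 of 6 arrays (camera adjusted p = 4.99e-06, and adjusted p = 0.39 with an estimated correlation). Of 11 hypothalamic markers 10 were lower, led by the neuropeptide precursors Avp (-0.95 ± 0.29), Oxt (-0.67 ± 0.28), Cartpt (-0.66 ± 0.17) and Hcrt (-0.51 ± 0.28), with an adjusted p of 0.000898 and an adjusted p = 0.39 with an estimated correlation. Of 13 microglial genes 11 were lower, among them C1qa (-0.58 ± 0.22) and Tyrobp (-0.46 ± 0.17), with an adjusted p of 0.000898 and an adjusted p = 0.61 with an estimated correlation. Of 18 endothelial and pericyte genes 15 were lower, with Tie1 at -0.44 ± 0.14 and Acta2 at -0.44 ± 0.27 (adjusted p = 0.0275, and adjusted p = 0.61 with an estimated correlation).

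Higher on the treated arrays were 15 of 17 glucocorticoid-responsive genes, with Sgk1 at 0.77 ± 0.35 and Plin4 at 0.51 ± 0.37 (adjusted p = 0.00735, and adjusted p = 0.65 with an estimated correlation). So were 13 of 18 clock genes, with Nr1d2 at 0.71 ± 0.37 and Bhlhe40 at 0.42 ± 0.22 (adjusted p = 0.0243, and adjusted p = 0.39 with an estimated correlation). Of 12 cerebellar markers 11 were higher on average (adjusted p = 0.0124, and adjusted p = 0.65 with an estimated correlation), with medians of -0.096 and 0.011 on day 1, 0.17 and 0.19 on day 3 and 0.25 and 0.60 on day 10, at 50 and 1250 mg/kg. Adjusted over the list alone, 2 hypothalamic genes were called and 0 in each of the other 6 lists. Among the brightest 6424 probes the calls of the cerebellar (adjusted p = 0.265), clock (0.126) and endothelial (0.323) lists ended, and the endothelial call also ended without day 3 (0.0506). The model takes the 6 treated arrays as independent, although arrays of a shared day deviated together (correlations across genes of 0.44 to 0.70). A single control array stands on the other side of all these values, so a property of that array would give the same signs on all 6 treated arrays.

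For time, 126 genes were higher and 48 lower on day 10 than on day 1. The highest were transcripts of the cerebellum and hindbrain: Pcp2 (4.15 ± 0.42, 2 arrays per day, adjusted p = 5.7e-05), En2 (2.45 ± 0.28, adjusted p = 0.000175), Dao (1.67 ± 0.29, adjusted p = 0.00893), Cbln1 (1.60 ± 0.24, adjusted p = 0.00247) and Zic1 (1.47 ± 0.15, adjusted p = 5.7e-05). Lowest among genes lower at both doses were Prl (-4.62 ± 0.60, adjusted p = 0.000761) and Gh (-3.74 ± 0.52, adjusted p = 0.00127), followed by the immediate early genes Fosb (-1.16 ± 0.12, adjusted p = 5.7e-05) and Egr2 (-0.97 ± 0.20, adjusted p = 0.0193) and the olfactory bulb transcript Cdhr1 (-0.97 ± 0.20, adjusted p = 0.0206). The share of higher genes among these calls was 72.4%, but 28.1% in the deposited values (131 higher, 336 lower) and 39.0% after median scaling (170 higher, 266 lower). Without the day 3 arrays, a model added after seeing the data, 212 were higher and 101 lower, and the 174 first called were all among them.

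Immediate early genes, which neurons induce within minutes of activity, were lower on day 10 as a group. Of 25 measured, 24 were lower than on day 1, with a median of -0.38. Fosb, Egr4 (-0.97 ± 0.12, adjusted p = 0.000562), Egr2 and Arc (-1.10 ± 0.26, adjusted p = 0.0377) were among 5 called over all genes, and 13 were called adjusted over the list alone. Camera gave an adjusted p of 3.55e-11, and an adjusted p = 0.53 with an estimated correlation. Against the control the list's median was 0.075 and 0.046 on day 1 and -0.41 and -0.28 on day 10 at 50 and 1250 mg/kg, and on day 10 it lay below all 10000 matched random lists at both doses. On the same arrays 14 of 15 markers of cortical and hippocampal neurons were lower, with a median of -0.26, and 11 of 12 cerebellar markers were higher, with a median of 0.53 (adjusted p = 0.68 with an estimated correlation for each). Of 17 glucocorticoid-responsive genes 16 were lower on day 10 (camera adjusted p = 7.14e-06, and adjusted p = 0.56 with an estimated correlation). Cdkn1a at -0.88 ± 0.18 (adjusted p = 0.0213) was the only call of that list over all genes, and 5 were called adjusted over the list alone. Among 18 clock genes, 1 higher and 2 lower were called over all genes, and 6 higher and 5 lower adjusted over the list alone. Camera, which looks for a shared direction, did not call the clock list (adjusted p = 0.57).

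Markers of brain regions moved apart between the days. Of 12 cerebellar markers 11 were higher on day 10, with a median of 0.53, 5 called over all genes and 9 adjusted over the list alone (camera adjusted p = 4.52e-11, and adjusted p = 0.68 with an estimated correlation). Of 6 hindbrain markers 4 were higher and 2 lower. Tph2 (1.41 ± 0.13, adjusted p = 3.86e-05) and Slc6a4, the serotonin transporter (0.89 ± 0.14, adjusted p = 0.00393), were called higher (camera adjusted p = 0.00211, and adjusted p = 0.68 with an estimated correlation). Of 15 markers of cortical and hippocampal neurons 14 were lower, with a median of -0.26, and Camk2a (-0.46 ± 0.11, adjusted p = 0.0385) was called (camera adjusted p = 1.36e-05, and adjusted p = 0.68 with an estimated correlation). All 13 microglial genes were lower with a median of -0.26 (camera adjusted p = 0.000658, and adjusted p = 0.68 with an estimated correlation). Of 11 hypothalamic markers 9 were lower, with Avp (-0.62 ± 0.12, adjusted p = 0.0183) and Hcrt (-0.54 ± 0.13, adjusted p = 0.0393) called (camera adjusted p = 0.0359, and adjusted p = 0.68 with an estimated correlation). Pituitary hormones had 3 measured members, too few for the list test, and all 3 were lower. Each day was 1 pair of arrays, so a difference between days cannot be told from a difference in the tissue taken or in the handling of that day.

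The title's reciprocal regulation was examined as opposite changes at the 2 doses. On day 3, Gh differed from the control by 2.24 at 50 mg/kg and by -0.76 at 1250 mg/kg, and Prl by 2.51 and -1.39. The falls at 1250 mg/kg ended near the floor of the values, with Gh going from 0.07 in the control to -0.69 and Prl from 0.91 to -0.49. The lowest deposited values of single arrays ran from -0.88 to -0.60. Gh and Prl were the only genes changed at least 1.5-fold in opposite directions on day 3, and day 1 and day 10 had 0. Independent lists of those sizes would give 0.148, 21.0 and 1.14 on days 1, 3 and 10, and simulations with a shared control a mean of 0.06 and at most 2. Among the brightest 6424 probes day 3 had 0. Below that threshold, ranked by the smaller of both changes, the leading genes lower at 50 and higher at 1250 mg/kg were Pcp2 on day 1 (-0.66 and 0.36 at 50 and 1250 mg/kg), S100a8 on day 3 (-0.84 and 0.51), and Dusp1, a phosphatase gene induced by stress, on day 10 (-0.51 and 0.57). Csf2ra on day 10 (0.36 and -0.37) and Smpd3 on day 1 (0.34 and -0.33) led in the other direction on those days. The fall of Pcp2 on day 1 also ended near the floor, from 0.04 in the control to -0.63 at 50 mg/kg, and its value at 1250 mg/kg was 0.40.

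**Figure D3:**
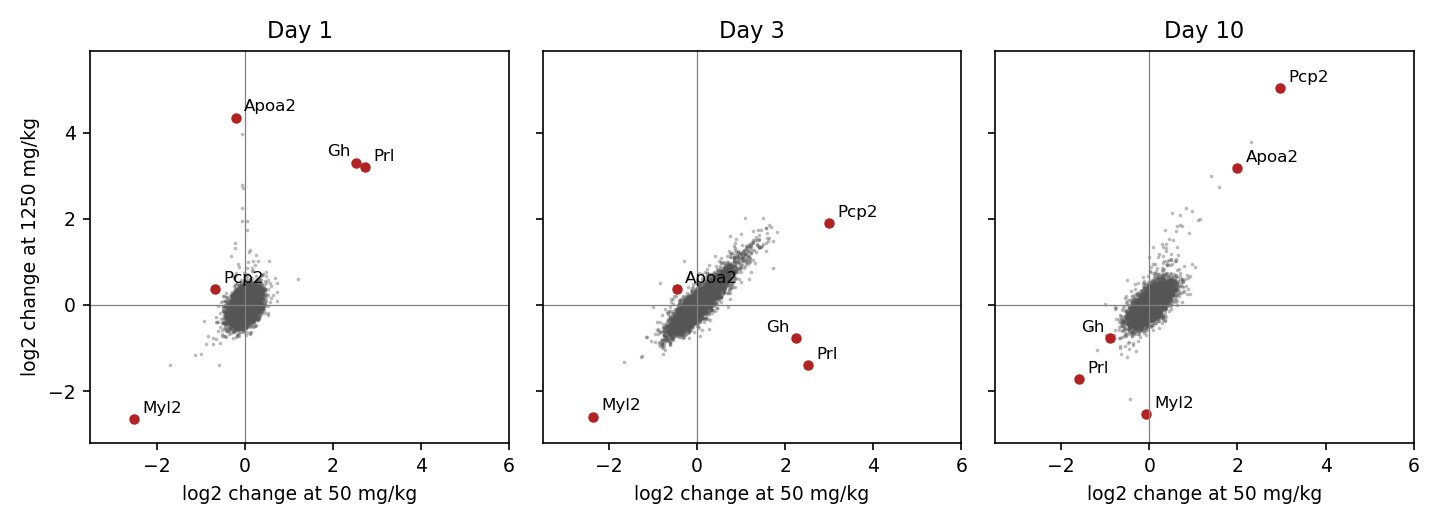
Log2 change against the control at 50 mg/kg (horizontal) and 1250 mg/kg (vertical) for each of 9009 genes on each day, with 5 genes named. Gh and Prl are in the lower right quadrant on day 3 and in the upper right on day 1, and the cloud of genes is most elongated on day 3, where the correlation is 0.881.

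Most genes that changed at both doses did so in a shared direction. Genes changed at least 1.5-fold one way at both doses numbered 15 on day 1, 478 on day 3 and 51 on day 10, beside 0.14, 30.8 and 1.46 for independent lists of those sizes and a mean of 2.26 in simulations of unchanged arrays with a shared control. Across genes, which are not independent replicates, the changes at the 2 doses correlated at 0.377 on day 1, 0.881 on day 3 and 0.681 on day 10, where the shared control alone gave 0.499. The covariance was 0.0156 on day 1, equal to the simulated 0.0156 at this precision, 0.102 on day 3 and 0.0391 on day 10. There is 1 control array, so part of the excess may come from it. The simulations also leave out what arrays of a shared day have in common (correlations of their deviations 0.58, 0.70 and 0.44 on days 1, 3 and 10).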

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

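The tests of explanations in this part were chosen after the results were seen, except the count of splits, and the search for arrays apart was extended to named genes and the added lists after a first look. For the liver profile and the second probes of day 3, a first, looser criterion had been met before both were made stricter. An array far from the other treated arrays was looked for in 89 list medians and named genes, and 3 were found, where chance gives about 5% of such groups. Myl2 on day 10 at 50 mg/kg lay at -0.076 against the control, while the nearest other array was at -2.36. Dusp1 on the same array was at -0.51, beside 0.18 on the nearest. The median of the oxidative stress list was 0.16 on day 1 at 1250 mg/kg, beside 0.032 on the nearest. Among the 1154 probes with no gene name here, which no comparison of the report uses, 2 were called for dose, both higher, and 39 for day 10 against day 1, 23 of them higher.

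The first pattern is the liver transcripts at 1250 mg/kg. Scaling between arrays is argued against by the sizes: the 9 called liver genes differed by 0.75 to 2.28. The median gene of an array differed from the control by -0.13 at the most in the deposited values. That 9 of the 9 stayed called under both other scalings was near certain for differences of that size and adds little. RNA from liver tissue in the brain sample stays open: the linear signal of the 24 measured liver genes above the control kept a similar profile on day 1 at 1250 and day 10 at both doses (smallest Pearson correlation across genes 0.869, smallest Spearman 0.714). For 49 other liver genes on the array, Alb among them, no value was used, and a missing value excludes nothing. The list lay 0.26 higher on day 10 at 50 than on day 3 at 1250 mg/kg, but these are single arrays of different days and decide nothing. Within each day its median was higher at 1250 than at 50 mg/kg (0.92 and -0.050 on day 1, 0.039 and -0.16 on day 3, 0.87 and 0.30 on day 10). A response to the dose, alike on all days or not, stays open with 1 array per condition.

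For the dose count, the real split of the 6 treated arrays called 13 genes. Of the 10 splits, only the real one and 3 others part the doses of every day. Those 3 called 1, 4 and 0, and they are too few for a share under 0.05. The rest leave both arrays of some days on 1 side, so with the day block they compare the doses of 1 day only. Their highest count, 10, came from the doses of day 10 and is no measure of chance.

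The second pattern is the change of cerebellar, hindbrain and pituitary transcripts between days. Scaling between arrays is argued against only by the size of the largest changes. In the deposited values the median gene differed from the control by 0.013 and 0.015 on day 1 and by -0.060 and -0.087 on day 10. The 10 named genes were chosen as the largest differences, so their calls under both other scalings were near certain and test little. Of these, Fosb, Egr2 and Cdhr1 lie outside the pattern. Scaling did turn the balance of all day calls, from 126 higher and 48 lower to 131 and 336 in the deposited values. A different share of brain regions and pituitary in the tissue taken stays open: 11 of the 12 measured cerebellar markers were higher on day 10, which restates the pattern and decides nothing. Days of dosing stay open as a biological explanation, since the length of dosing and the time the tissue was taken go together in this design. For the pituitary part, Gh and Prl differed by a mean of 3.45 between both arrays of day 3, which days of dosing alone leave unexplained.

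The third pattern is that both day 3 arrays stand apart from the rest. Scaling between arrays is argued against, since the excess was there with and without quantile normalization. With it, at least 105 genes were 2-fold higher on each, beside at most 40 on the other treated arrays. In the deposited values at least 83 were higher on each, beside at most 36. A probe-dependent signal, as from RNA quality or labelling, stays open: a second probe of the same gene showed at most 0.43 of the change of the first on the day 3 array not used to choose the genes, but this share ran from 0.14 to 0.89 on other arrays and the second probe is by rule the dimmer. An effect of 3 days of dosing stays open too, since both arrays differed from the mean of the other 5 in a shared way (Pearson correlation across genes 0.837), and shared handling of the day would give the same.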

How the results depend on the processing

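The models without day 3 and with the liver list were chosen after seeing the data. No value could be computed without background correction or without the authors' filter, because intensities could not be tied to samples and blank probes have no value. Against the control at least 2-fold, 6, 24, 113, 147, 12 and 48 genes (day 1, 3 and 10, 50 before 1250 mg/kg) became 1, 4, 39, 46, 5 and 13 among the brightest 6424 probes, where fewer genes were tested, and 28, 94, 631, 739, 125 and 188 at 1.5-fold. For dose, 13 calls became 2 in the brightest 6424 probes, 0 with no day block and 7 to 45 in leave-one-out models. With the liver list as a covariate 2 were called (Gh and Prl, lower). Without it, Gh and Prl differed by 0.77 and 0.48 on day 1, -3.00 and -3.90 on day 3 and 0.12 and -0.12 on day 10, so these calls rest on a difference that the days did not share. Of the 13 first called, 9 are members of the liver list, so losing their calls is built into the covariate and tests nothing. The other 4 lost theirs too, at 0.69 for Sgk1, 0.33 for Ddit4, 1.20 for S100a8 and 0.96 for Vapa, beside 0.68, 0.61, 0.90 and 0.65 without the covariate. For Sgk1, S100a8 and Vapa the difference was no smaller with the covariate, so a smaller difference is not why their calls were lost. The list members Apoa2 (-0.60), Apoa1 (-0.18), Apoc3 (-0.12) and Fgg (-0.042) turned sign there, none past the threshold. Leave-one-out dose differences ran from -0.037 to 1.54 for Pcp2, -0.11 to 0.75 for Cbln1 and -0.0096 to 0.29 for Slc6a4. The negative ones, without day 10, missed the threshold, and those of Pcp2 and Cbln1 without day 3 passed it. For treatment, leave-one-out models called 0 to 1. For day 10 against day 1, 174 calls became 467 in the deposited values (140 shared), 436 after median scaling (151 shared) and 313 without day 3. Opposite changes on day 3 fell to 0 in the brightest 6424 probes and 1 at 2-fold. The 8 lists called for dose became 4 in the brightest 6424 probes. With an estimated correlation 0 lists were called for dose, treatment or day. The cause was not tested where fewer genes or arrays do not show it. The other 45 planned counts stayed within 1.5 times, as did 4 added ones. Of planned values of single genes or lists, 757 kept direction and side of the threshold, 39 newly passed it, 26 no longer did and 4 moved. Signal over background is unknown, and it limits dim genes most.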

Other observations

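The heart and skeletal muscle list and the models without day 3 were chosen after the results were seen. Transcripts of heart muscle were higher in the control than on most treated arrays. Of 22 measured genes of that list, 18 were lower on the treated arrays, with Myl2 at -2.12 ± 0.75, Nppa at -1.45 ± 0.44, Myl4 at -0.79 ± 0.34 and Tnnc1 at -0.73 ± 0.32, none past the threshold. Myl2 passed it only without the array of day 10 at 50 mg/kg, the 1 array where it lay near the control, so leaving that array out sets the outcome. At 50 and 1250 mg/kg, the list's median against the control was -0.11 and -0.20 on day 1, -0.44 and -0.48 on day 3, and -0.081 and -0.27 on day 10. It did not closely follow Myl2 from array to array. On day 1 at 50 mg/kg Myl4 was at -0.29 and Myl2 at -2.50, and on day 10 at 50 mg/kg Myl4 was at -0.66.

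Other marker lists were also called between day 10 and day 1. Of 18 oligodendrocyte and myelin genes 14 were higher on day 10, with Trf, the iron carrier transferrin, at 0.43 ± 0.12 (camera adjusted p = 0.0359, and adjusted p = 0.68 with an estimated correlation), a call that ended in the deposited values (adjusted p = 0.887) and after median scaling (adjusted p = 0.913). Of 15 choroid plexus genes 12 were lower (adjusted p = 0.0226) and all 7 genes of ependymal cilia were lower (adjusted p = 0.0457), each with an adjusted p = 0.68 with an estimated correlation. Both calls ended in the deposited values (adjusted p = 0.0983 and 0.221) and after median scaling (adjusted p = 0.106 and 0.234), the ependymal call also without day 3 (adjusted p = 0.0517). Of 19 dopamine signalling and striatal genes 15 were lower (camera adjusted p = 0.0177 for the list, and adjusted p = 0.68 with an estimated correlation). Drd2, a dopamine receptor, was at -0.43 ± 0.14 and Slc6a3, the dopamine transporter, at 0.48 ± 0.16, and neither passed the test.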
